A study of Arabidopsis thaliana with 4 samples.

How the data were processed

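Chromatin immunoprecipitation followed by hybridisation to a genome tiling array (ChIP-chip) was used to map histone H3 dimethylated at lysine 27 (H3K27me2) in Arabidopsis thaliana seedlings of the Col-0 ecotype, labelled as 10 days old. Each hybridisation set DNA recovered with an H3K27me2 antibody (the IP) against the input DNA of the same preparation, one labelled with Cy3 and the other with Cy5. The labels give 2 preparations, I and II, called replicate 1 and replicate 2 here, and each was hybridised on 2 arrays with the dyes exchanged, so that 4 arrays form 1 group. Nothing in the labels says whether the preparations came from separately grown plants, so no p-value here speaks beyond these 2 samples. The p-values of single probes rest on a spread between the 2 samples that was pooled over probes. Those over shifts of the address order rest on how the 2 samples line up along the addresses.

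The authors deposited 1 table with a signed score per probe and array. How these deposited scores were made (background correction, normalisation within the array, combination of the dye swaps, logarithm and its base) is not given in the sources used here. By their sign and range they look like log ratios, but the base is unknown. A distance of 1 unit would be a factor of 2 only if the base is 2, and no fold change is therefore given. The table has 21800 rows with no repeated ID. Of these, 21690 hold a value in all 4 columns and 110 hold none. The 39 rows without a plate and well address are all among the 110. No column belonged to another sample.

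The 2 columns of each dye swap were compared cell by cell. In replicate 1 all 21690 probes were identical between the columns (largest difference 0.0), and so they were in replicate 2. Each pair was therefore counted as 1 value per probe, with n = 2 replicates. The identity of the columns means that the deposited scores already combine or copy the dye orientations. It also means that neither the dye effect nor the spread between arrays of one preparation can be measured from these values. The direction of the score (IP over input or the inverse) is not settled by the labels, since the column with the IP in Cy5 and the column with the IP in Cy3 hold the same numbers. Scores are therefore called higher or lower than the median of their replicate, without assigning enrichment or depletion. If the score is input over IP, a higher score means less IP signal, and turning the sign of both replicates swaps "higher" and "lower" without changing any count or correlation. The positive correlation between the replicates gives no sign that they were turned against each other. Since the dye effect cannot be measured, it does not settle this.

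Probe IDs are addresses made of a 2-letter prefix (TA, TB, TC, TD or PD), a plate number, a row letter and a column number, over 231 plates of up to 96 wells. None of the 21690 probe IDs with a value matched a gene ID, symbol, synonym or accession among the 38312 genes of the reference table (TAIR10.1), and no probe positions or sequences were used here. The planned comparisons of genes, transposable elements, chromosome windows and positions along genes, and of the 5 gene lists with 63 members fixed before the data were examined (Polycomb targets, genes expressed in most tissues, cold-inducible CBF genes, genes silenced by DNA methylation, and flowering and meristem genes), could not be placed on probes and have no result. At most 2 probe IDs in each direction are named.

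Each replicate was centred on its median, with no loess or quantile normalisation, since many probes of a ChIP array can carry signal. Probes were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, Benjamini-Hochberg adjusted p under 0.05), with 1 residual degree of freedom per probe. The prior degrees of freedom were infinite, so every probe received the same standard deviation of 0.672 per replicate. A second count, free of any estimated spread, took probes at least 1 unit from the median on the same side in both replicates. The named probes are those with the most extreme mean among the probes past the threshold with the same sign in both replicates, a rule fixed before the data were examined. The planned per-array spread, dye term and single-dye fits could not be run on identical columns.

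Chance agreement was judged by moving replicate 2 along the order of addresses against replicate 1, over all 21499 circular shifts of at least 96 addresses, which keeps the similarity of neighbouring probes. The p-values over shifts are approximate, since shorter shifts were left out and the level of the scores differed between plates. Runs of calls, stretches of plates and pairs of extreme probes were also compared with 1000 shuffles each, but these ignore the similarity of neighbouring probes and are not used. Intervals are 95% bootstrap intervals from 1000 resamples of whole plates, except for the upper tail of replicate 2. There single probes were resampled, which ignores the similarity of neighbouring probes. The fixed plan held a correlation of neighbouring probes only for probes with coordinates, so these analyses of the address order were chosen after seeing the table. They used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

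The procedures were tested on simulated data. For 21690 probes in 2 replicates with the fitted spread, limma recovered 78.0% of 50 probes moved by 2 units and 100.0% of 50 probes moved by 3 units, with 10 false calls among 199. This simulation had independent noise of the same spread in every probe and both replicates, with all unmoved probes at 0. In the deposited scores the difference between replicates was similar at neighbouring addresses (r = 0.610). The standard deviations of the replicates were 1.05 and 0.759. The share of false calls in the deposited scores is therefore not known from it. For values simulated at the real addresses with a neighbour correlation of 0.6, the recovered correlation was 0.599. Unrelated simulated replicates gave a p of 0.490 over the shifts and replicates sharing a signal gave 4.65e-05. Alternatives covered the centring (none, mode), equal spread, quantile normalisation, the variance model, the thresholds, a minimum change, a mixture model, the size limit, each replicate alone, plate medians and smoothing. The arrays give no read depth, and precision is limited by the 2 replicates.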

Results

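H3K27me2 is a histone mark placed by the Polycomb repressive machinery and is found in silent chromatin. The series was designed to map it in Arabidopsis seedlings as part of a reference epigenome, by setting immunoprecipitated DNA against input DNA on a tiling array. The data consisted of 4 two-colour arrays from 2 replicates, each hybridised in both dye orientations, with a score for 21690 probes. The 2 columns of each dye swap were identical, so each probe had 1 score per replicate. In replicate 1 the deposited scores had a median of -0.26, a standard deviation of 1.05 across probes and a range from -3.49 to 3.34. In replicate 2 the median was -1.24, the standard deviation 0.759 and the range -4.54 to 3.55. Neither replicate was centred on 0, and the medians lay further apart than the standard deviation of replicate 2. All values below are distances from the median of the replicate, in deposited units of unstated log base, and whether a high score stands for IP over input or the inverse is not settled.

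The first comparison asked whether the profile of scores was shared by the 2 replicates. Probes that scored high in one replicate tended to score high in the other, with a Pearson r across probes of 0.49 (95% interval 0.459 to 0.523, plates resampled) and a Spearman rho of 0.472. Probes are not independent replicates, and this correlation is across probes within 2 samples. In an exact one-sided test over all 21499 circular shifts, no shift reached the observed r (highest 0.0746, p = 4.65e-05, the smallest the shifts can give). Scores lay on the same side of both medians for 64.1% of probes. The standard deviation of the difference between replicates was 0.944 across probes. The common standard deviation between the 2 replicates of a probe, as limma estimated it, was 0.672, and the standard deviation of the mean of the replicates across probes was 0.783.

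**Figure D1:**
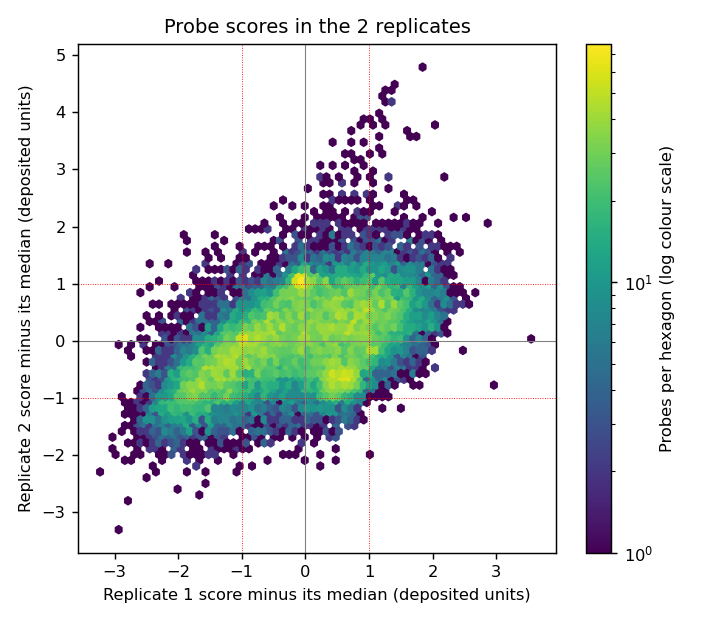
Score of each of the 21690 probes in replicate 1 (x axis) and replicate 2 (y axis), each minus its replicate's median in deposited units; colour gives the number of probes per hexagon on a log scale and dotted lines mark 1 unit. The scores follow each other with r = 0.49, and a sparse tail of probes reaches 4.79 in replicate 2.

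The agreement between replicates differed between parts of the array, though the differences were not tested. The probes fall into 5 address sets of unequal size. In the TB set, with 9571 probes on 100 plates, r between replicates was 0.602. In the TA set, with 9296 probes on 99 plates, it was 0.456. It was 0.269 in the TC set, with 2411 probes on 27 plates. The small PD and TD sets, with 316 and 96 probes, had r of 0.566 and 0.685. The median of the TA set was 0.344 in replicate 1 and 0.0496 in replicate 2, and that of the TB set was -0.381 in replicate 1 and 0.0486 in replicate 2. The TA and TB sets thus lay apart in replicate 1 and close together in replicate 2. The median of the TC set was 0.173 in replicate 1 and -0.308 in replicate 2. In the TD and PD sets the medians were below 0 in both replicates, with means of -0.62 ± 0.142 (SD, n = 2) and -0.202 ± 0.0276 (SD, n = 2).

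The second comparison asked which probes differed from the bulk of the array in the IP against the input. Of the 21690 probes, 1672 passed an adjusted p of 0.05 with limma and Benjamini-Hochberg adjustment, of which 505 (2.33%) were higher and 1167 (5.38%) lower than the median. All 1672 had the same sign in both replicates. As every probe received the same spread, a call amounted to a mean at least 1.37 from the median. Such a mean with opposite signs needs a very extreme score in 1 replicate, so the shared sign is no separate evidence of agreement. The 505 higher probes had a median mean score of 1.53, with medians of 1.72 in replicate 1 and 1.40 in replicate 2. The 1167 lower probes had a median mean score of -1.57, with medians of -2.00 in replicate 1 and -1.21 in replicate 2. Lower calls made up 11.5% of the small TD set (11 of 96 probes), 6.54% of the TB set, 5.70% of the PD set, 4.41% of the TA set and 4.23% of the TC set. Higher calls made up 2.76% of the TA set, 2.41% of the TB set, 1.27% of the PD set and 0.539% of the TC set, and the TD set had 0. These shares were not tested against each other.

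The probe with the highest mean, TB40E11, scored 1.86 in replicate 1 and 4.79 in replicate 2, a mean of 3.33 ± 2.07 (SD, n = 2; limma adjusted p = 5.52e-08). TA32F08 followed with 1.39 and 4.50, a mean of 2.94 ± 2.20 (SD, n = 2; limma adjusted p = 4.27e-06). For both, the replicates lay far apart, which the limma test does not register because it gave every probe the same spread. The lowest probe, TA58A11, scored -2.93 and -3.30, a mean of -3.12 ± 0.260 (SD, n = 2; limma adjusted p = 5.75e-07). TA21A05 scored -2.79 and -2.85, a mean of -2.82 ± 0.0438 (SD, n = 2; limma adjusted p = 9.10e-06). For these the replicates lay close together. No gene, repeat or position can be given for these probes.

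The number of calls depended on how the spread was modelled and on the choice of the zero level. With a trended, robust prior, limma called 3 probes, all lower, among them TA58A11 and TA21A05, while 4246 had an unadjusted p under 0.05. Without centring it called 0, with 5660 at an unadjusted p under 0.05. Centring on the mode of each replicate in place of its median gave 1756 calls, of which 62 were higher and 1694 lower. The split of higher and lower calls thus depends on where 0 is placed. It also turned with 0 left at the median, where a test against a change of 0.5 called 23 higher and 13 lower. A 2-component mixture split the scores into broad parts with weights of 40.5% and 59.5% and means of -0.717 and 0.419. In that fit the median used as 0 lay between the 2 means. No fit with 1 component was compared, so the mixture cannot decide whether a single bulk of the array lies around 0.

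A count that needs no estimate of the spread took the probes at least 1 unit from the median on the same side in both replicates. There were 1834 such probes (8.46%), 634 higher and 1200 lower. Taken alone, replicate 1 had 3314 probes at least 1 unit above and 4981 below, and replicate 2 had 2018 above and 1827 below. More lower than higher probes were thus seen in replicate 1 and not in replicate 2. Independent replicates would have given 308.3 higher and 419.6 lower. Over the circular shifts the total had a median of 726 and a maximum of 882 (one-sided p over the shifts = 4.65e-05, the smallest the shifts can give). Probes past 1 unit on opposite sides were rare. There were 50, against a median of 745 and a minimum of 587 over the shifts. Of these 50, 46 were low in replicate 1 and high in replicate 2. This direction depended on the size. At 0.585 units, 332 probes were low in replicate 1 and high in replicate 2, and 636 the other way. At a distance of 2 units in both replicates, 6 higher and 12 lower probes remained.

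The third comparison asked whether probes with high and with low scores lay in blocks. Probes at consecutive addresses had similar scores, with r of 0.763 in replicate 1 and 0.503 in replicate 2 over 21534 pairs. The similarity fell with distance, to 0.419 and 0.224 at 4 addresses, 0.239 and 0.113 at 12, and 0.121 and 0.0454 at 96. Scores of replicate 1 also went with those of replicate 2 at the next address (r = 0.368). The difference between replicates was itself similar at neighbouring addresses, with r of 0.610 at 1 address and 0.204 at 96.

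**Figure D2:**
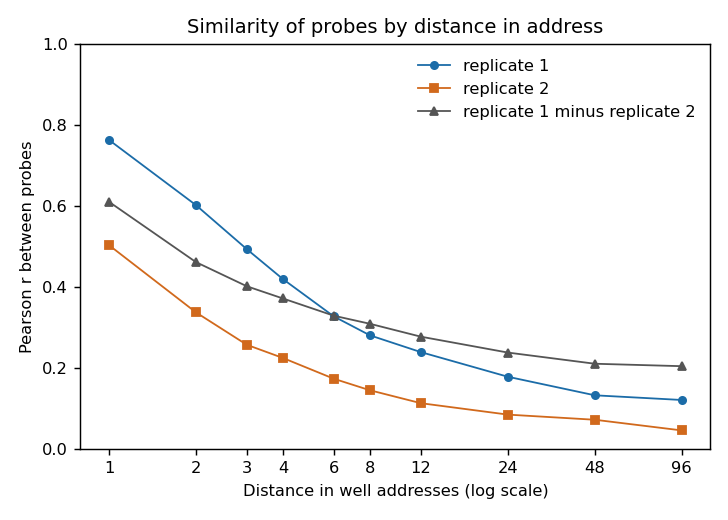
Pearson r between probes a given number of well addresses apart (x axis, log scale) for replicate 1, replicate 2 and their difference. The r falls from 0.763 to 0.121 in replicate 1 and from 0.503 to 0.0454 in replicate 2, while that of the difference stays at 0.204 at 96 addresses.

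Probes past the threshold also formed runs, which are expected where neighbours are similar and are described here without a test. Of the 1167 lower probes, 260 (22.3%) lay in 74 runs of at least 3 consecutive addresses, and the longest run had 9 probes. Of the 505 higher probes, 123 (24.4%) lay in 30 such runs. The longest run of lower probes, on TA plate 87, had means of -2.01 in replicate 1 and -1.26 in replicate 2. The longest run of higher probes had 13 members on TB plate 25, with means of 2.17 in replicate 1 and 0.872 in replicate 2. It lay within stretches where consecutive probes had almost constant scores. With all such flat stretches left out, the longest run of higher probes had 6 members and 86 of 465 higher probes remained in runs. For lower probes, 254 of 1161 remained in runs and the longest had 6.

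**Figure D3:**
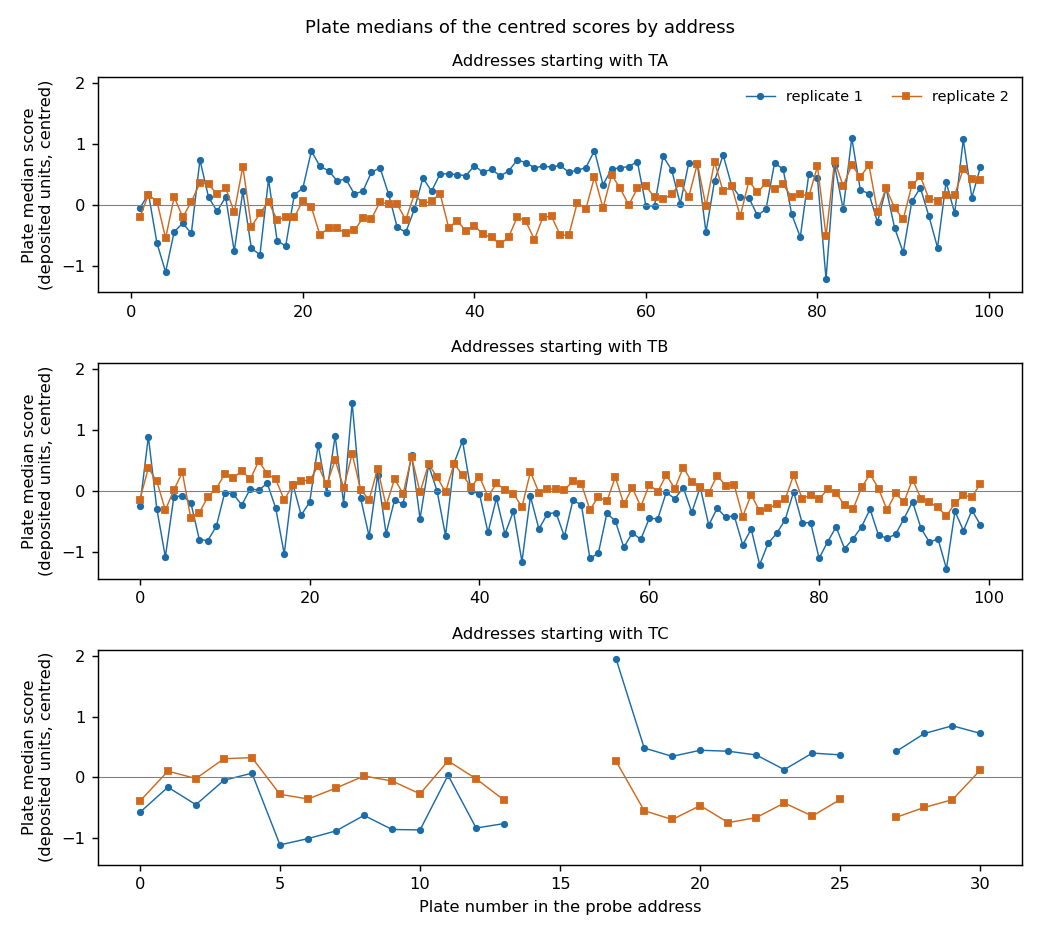
Median centred score of each plate (y axis, deposited units) by plate number in the probe address (x axis) for the TA, TB and TC sets; circles are replicate 1 and squares replicate 2, and gaps are plates without probes. On TA plates 37 to 51 the medians of replicate 1 lie above 0 and those of replicate 2 below 0.

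The plates also differed from one another. Plate means accounted for 22.1% of the variance of replicate 1 and 11.6% of that of replicate 2, whereas the row letter accounted for 0.174% and 0.12% and the column number for 0.00777% and 0.172%. Plate medians differed by at least 0.6 on 37 of the 231 plates with replicate 1 above and on 36 with replicate 2 above. By the rule given below, the replicates parted over 3 stretches of plates where replicate 1 lay above replicate 2. On TA plates 37 to 51, with 1349 probes, the median was 0.587 in replicate 1 and -0.44 in replicate 2, and the plate medians lay on opposite sides of 0 on all 15 plates. On TA plates 21 to 26, with 523 probes, the medians were 0.525 and -0.361. On TC plates 17 to 22, with 538 probes, they were 0.46 and -0.579, with opposite signs on 5 of the 6 plates. The stretches were defined after seeing the data, as at least 5 consecutive plates whose median in replicate 1 exceeded that in replicate 2 by at least 0.6. TC plates 24 to 29 fall outside it only because no plate 26 holds probes. These 5 plates, with 434 probes, all passed the 0.6 (0.732 to 1.21), and with missing plates skipped they form 1 more stretch. With the rule turned round, 1 stretch of 5 plates was found, TC plates 5 to 9. Within the 3 stretches r between replicates was 0.187, and over the remaining probes it was 0.56. The scores also spanned a narrower range there, which lowers r by itself. The standard deviation across probes was 0.569 inside and 1.07 outside in replicate 1, 0.603 and 0.767 in replicate 2, and 0.748 and 0.901 for the difference between replicates. The choice of plates by their difference partly fixes these values and both r, so they do not measure how well the replicates agree there. Of the 2410 probes in them, 23 were called higher and 10 lower.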

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

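The number of probes past the threshold, 1672, stayed within 1.5 times under mode centring (1756, keeping 1229 of the 1672), equal median absolute deviations (2015, keeping 1653), quantile normalisation (2265, keeping 1671) and a mean over 3 consecutive addresses (2034, keeping 1055), so part of the called probes changed. It moved beyond that to 0 without centring, 3 with a trended and robust prior, 275 at an adjusted p of 0.01, 36 when tested against a change of 0.5, 2717 with plate medians subtracted (keeping 1164) and 2863 for the smaller component of a 2-component mixture (posterior above 0.95). Higher calls were 30.2% of the calls, against 3.53% with mode centring, 63.9% when tested against 0.5 and 44.1% with plate medians subtracted. The prior with a trend kept no higher call. The smaller component (weight 40.5%, mean -0.717, SD 0.569) had its 2863 probes all below the median. The larger (59.5%, 0.419, SD 0.536) had its 5012 all above. Neither is a small class. The count past 1 unit in both replicates, 1834, became 5718 without centring (23 higher and 5695 lower), 5474 at a size of 1.5-fold if the base is 2 and 18 at 4-fold. It was 3845 without replicate 1, with 52.5% higher, and 8295 without replicate 2, with 40.0% higher. With mode centring it was 1968, with 9.65% higher in place of 34.6%. The r between replicates moved from 0.49 to 0.535 with plate medians subtracted, to 0.56 without the plate stretches where the replicates parted, to 0.579 with missing plates skipped in defining them and to 0.524 without flat windows. The correlation of consecutive addresses of the mean, 0.696, was 0.503 to 0.763 with 1 replicate left out and 0.648 with plate medians subtracted. The 4 named probes kept their sign under all settings run. Their choice by an extreme mean with the same sign in both replicates largely fixed this in advance. Each of the 4 lost its call without centring. TB40E11 and TA32F08 also lost theirs with the trended, robust prior (adjusted p = 0.131 for both), and TA32F08 and TA21A05 with the mean over 3 consecutive addresses (adjusted p = 0.215 and 0.0551). The adjusted p over the 9 alternatives ranged from 1.49e-11 to 0.142 for TB40E11, 1.22e-11 to 0.215 for TA32F08, 1.21e-12 to 0.142 for TA58A11 and 1.39e-11 to 0.142 for TA21A05. Where the alternative's own construction does not show it, the cause was not tested. Settings with plate medians, smoothing, plate stretches or flat windows, and the correlation of consecutive addresses itself, were chosen after seeing the data. No paired analysis was possible because the design has a single group. Single-dye fits, fits with the replicate as a random block and a dye term were not run because the dye-swap columns are identical, nor were copies treated as independent arrays. Limma has no residual degrees of freedom with 1 replicate left out, so its count has no such value.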

Other observations

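The tests of noise of single probes, of chance overlap of flat windows and of the correlation outside the plate stretches were chosen after the results were seen. Those of plate position, plate offset, genome order, scale and single spots in the upper tail were written down after the similarity of neighbours had been seen, but before the values that decide them. Plate position and genome order were judged by the same correlations across the ends of plate rows. Some stretches of consecutive addresses held almost constant scores in both replicates, over different levels. In the longest, 38 probes on TC plate 17 scored 1.94 in replicate 1 with a standard deviation of 0.115 across probes, and 0.291 in replicate 2 with a standard deviation of 0.0746. A stretch of 30 probes that begins on TB plate 24 scored 2.12 (SD 0.123) in replicate 1 and 0.77 (SD 0.119) in replicate 2, and 25 of its probes were called higher. Others lay near 1.11 and -0.175 (17 probes, TC plate 29) and near 0.62 and -0.65 (13 probes, TA plate 42). There were 30 such stretches of at least 10 probes, some of them overlapping. All 30 lay above the median of replicate 1, and 22 lay below that of replicate 2. The mean of replicate 1 exceeded that of replicate 2 by 0.965 to 1.74 in these stretches. The flat windows overlapped with the 3 plate stretches where the replicates parted. Of the 1052 probes in flat windows, 58.2% lay in those stretches, which hold 2410 of the 21690 probes. With missing plates skipped, which adds TC plates 24 to 29, it was 79.7% in 2844 probes. Whether this share exceeds chance was not tested.

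Windows of 6 consecutive addresses with a standard deviation under 0.2 in both replicates numbered 460 of 21058, against at most 232 over the circular shifts (one-sided p over the shifts = 4.65e-05, the smallest the shifts can give). This argues against a chance overlap of flat windows between the replicates. A candidate explanation is that probes of repeated or nearly identical sequence sit at these addresses, which was not tested since no probe sequences were used here.

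Consecutive addresses held similar scores. A pair that follows across the end of a plate row lies far apart on the plate, yet its r was 0.739 in replicate 1 and 0.486 in replicate 2, close to the 0.765 and 0.505 within a row, and wells of the same column in the next row reached 0.246 and 0.115. This argues against the position in the 96-well plate. Subtracting each plate's median left 0.701 and 0.445, which argues against a shared offset of each plate as the whole cause. Addresses that follow the order of the probes in the genome, with signal domains that span several probes, would give such row-end values. This is no separate test of genome order, since the same row-end values were used against the plate position. The place of the spots on the slides was not used here, so a bias by place on the slide that follows the address order stays open.

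The difference between the replicates also ran in stretches. Its r at consecutive addresses was 0.610 (95% interval 0.584 to 0.633), which noise of single probes would leave near 0. With plate medians subtracted the r was 0.477, and in the residual of an orthogonal regression, which removes a different scale of the replicates, it was 0.461, so neither an offset per plate nor a change of scale accounts for the whole. Outside the 3 plate stretches it was 0.558. The difference may come from the preparations, their amplification or their hybridisation, which the deposited values cannot separate, and no biological explanation was tested since the design has a single group.

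In replicate 2, 66 probes lay over 2.5 above the median, against 8 in replicate 1. At 2 above the median the order was reversed (144 against 208), and replicate 1 had more probes over 2.5 below it (78 against 4). All 66 were above the median in replicate 1, where their own median was 0.946 (95% interval 0.763 to 1.09, single probes resampled). Noise alone, on probes without a shared signal, would leave replicate 1 near 0, and these values argue against that. Noise added to probes already raised in both replicates would also leave replicate 1 above 0, and the values do not tell against it. For probes over 1.5 and over 2 above the median in replicate 2, the medians in replicate 1 were 0.838 and 0.869. The direct neighbours of the 66 probes had a median of 0.232 (95% interval 0.0137 to 0.564, single probes resampled) in replicate 2. The rule written down also asked for clearly raised neighbours, so by that rule noise was not decided. How much noise added to the height of the tail stays open.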
